A study of Mus musculus with 23 samples.

How the data were processed

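Pooled guide RNA screens were analysed from mouse embryonic stem cells that carried Cas9 and a GFP reporter. The reporter transcript ended either in a control 3' untranslated region (UTR), named for the nematode gene unc-54 in the sample titles, or in the same region with 5 TRIM71 binding sites (5xT71BS), named for the nematode gene mab-10. Cells were transduced with a lentiviral guide library and sorted on day 8 into GFP-high and GFP-low fractions, and guides were counted by sequencing of genomic DNA.

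The values analysed were raw read counts per guide and library, deposited by the authors, whole numbers with no normalisation per the file headers and the values themselves. Per the submitters' processing notes, bcl2fastq 2.20 and Bowtie were used, and the Bowtie version is not given in the sources used here. DNA was isolated by phenol and chloroform extraction per the labels' protocols. The rules for mismatches and for reads that hit several guides are not given in the sources used here. Reads from amplified genomic DNA carry no molecular identifiers, so reads are not independent cells, and binomial intervals cover counting error only.

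There were 23 libraries, 1 in each group of screen, guide pool, reporter, fraction and day. The genome-wide screen had 18 libraries in 2 guide pools that hold mostly different genes, and the validation screen had 5. No group had a replicate library, so no test within a screen could use a spread between replicate libraries. Separate sorts exist for genes in both screens and for the few guides in both pools, which were compared by correlation and by calls, and no test of single genes over them was run. A count model such as the quasi-likelihood test of edgeR was therefore not used for any p-value. The guides of a gene are repeated perturbations of that gene within a library, and they served as the units of the test. Groups follow titles and genotypes in the labels. The culture text of the control samples names cells of the 5xT71BS reporter, which disagrees with their titles and genotypes, and the identity of the reporter in those libraries rests on the latter.

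Counts were scaled to the library total within each guide pool, a pseudocount of 10 was added, and the log2 ratio of GFP-high over GFP-low was taken for each guide and centred on the median guide of the pool. Guides entered with a mean count of at least 20 over the libraries compared, and genes with at least 3 such guides. The score of a gene is the median over its guides, and the error given is the SD over its guides. A two-sided guide permutation test compared each score with 1000000 random guide sets of the same size from the same pool, with Benjamini-Hochberg adjustment over all genes of the comparison and a threshold of 0.05. The smallest p the permutations can give is 2e-06. The test asks whether the guides of a gene stand apart from other guides of the same libraries, and it holds no information on the spread between separate sorts. For the reporter difference, the control log2 ratio was subtracted from the 5xT71BS log2 ratio of the same guide, and the same test was applied. Depletion in culture was scored in the same way from unsorted cells over the plasmid library. Of the genes, 97 had guides in both pools and were tested in the pool with more guides.

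The comparisons, the test, 28 gene lists and the rule for naming genes were chosen before the data were examined. The rule took every tested member of the lists of TRIM71 with its regulators, of the core of the microRNA-induced silencing complex, of microRNA biogenesis, of 4EHP-GIGYF repression and of nonsense-mediated decay, and at most 4 called members per direction of every other list. It also took the 10 called genes of largest score per direction in each comparison, and the genes called the same way in both screens for the reporter difference. The values of many genes that the rule takes are not reported here. For most lists, the members called over all genes are given with those called when p was adjusted over the list alone. The percentile of a list median among 10000 random lists of the same size, matched on mean guide count, describes these libraries and is not a test across libraries. The comparison of the unsorted lines, 8 further gene lists and 4 alternative settings were chosen after seeing the data.

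Guides without a gene symbol numbered 315 and 269 in the genome-wide pools and 13 in the validation library. They stayed out of the library totals used for scaling, of the median used for centring and of the random guide sets. Their share of reads lay between 0.51 and 0.738% in the genome-wide libraries and between 0.077 and 0.263% in the validation libraries, with 95% Wilson intervals at most 0.006 percentage points wide. Gene identifiers in the files matched the RefSeq gene table of GRCm38.p6 for 99.92 and 99.91% of named guides in the genome-wide pools and 99.96% in the validation library, and that table was used for current symbols alone. No genome build is named in the files, so no coordinates are given.

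The test was checked on simulated counts with known changes before it was run on the data. In the simulated 5xT71BS comparison of the genome-wide screen, over 17916 genes, it recovered 32.7% of log2 changes of 0.25, 98.0% of 0.5 and 100.0% of 1.0, with 4 false calls among 167. In the simulated genome-wide reporter difference, over 17914 genes, 8.2, 83.7 and 100.0% of the same changes were recovered, with 5 false calls among 149. In the simulated 5xT71BS comparison of the validation screen, over 2389 genes, 18.0% of log2 changes of 0.5, 80.0% of 1.0 and 100.0% of 2.0 were recovered, with 1 false call among 150. In the simulated validation reporter difference, over 2387 genes, 4.0, 44.0 and 98.0% were recovered, with 1 false call among 124. These simulations drew all guides of a gene with the same change and hold no cell-level scatter beyond that built from the counts. They also left most genes unchanged. In the validation data the difference had an SD of 1.118 over all guides and 0.7 over receptor guides, which widens the random guide sets. The smallest absolute score called there was 1.42 with 5xT71BS and 2.37 in the difference. The simulated recovery in the validation screen therefore does not carry over to the data. In both screens the simulated scatter of every guide was taken from olfactory receptor guides. In the genome-wide data with 5xT71BS, the median SD over guides was 0.262 for genes depleted in culture and 0.119 for others. The simulated share of false calls therefore does not carry over to depleted genes of the genome-wide screen.

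Alternatives covered the pseudocount, the count minimum, the scaling and centring, the mean in place of the median, the moderated test of limma 3.58.1 on guide log2 ratios, random guides matched on abundance, leaving out the most extreme guide of each gene, a minimum of 4 guides, and the unsorted fraction in place of a sorted one. Scaling and centring move scores and random guide sets together, so they can change calls almost only through the random draws and are a weak check. They are included in all counts of alternatives given below. edgeR 4.0.16 supplied TMM scaling factors alone. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9 and R 4.3.3 were used. An EGFP coding sequence used in the closing section was written from general knowledge and not taken from the data, and the labels name EGFP without its sequence.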

Results

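Mouse embryonic stem cells with Cas9 and an EGFP reporter were screened with pooled guide RNAs for genes that alter silencing by TRIM71, an RNA-binding protein of stem cells. The 5xT71BS reporter carried 5 TRIM71 binding sites in its 3' UTR, and the control reporter carried the unc-54 3' UTR. The genome-wide screen held 89915 guides against 18437 genes in 2 pools. Its 18 libraries came from GFP-high and GFP-low cells sorted on day 8, from unsorted cells of days 4 and 8, and from the plasmid pools. The validation screen held 11985 guides against 2397 genes, and its 5 libraries came from GFP-high and GFP-low cells of both reporters and from the plasmid library. Each library was the only sample of its group, so the errors given are SDs over the guides of a gene, not over repeated sorts.

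The 16 cell libraries of the genome-wide screen held 30810253 to 53255503 reads, with medians of 644 to 1274 reads per guide, and the plasmid pools held 83646677 and 198357174. The 4 cell libraries of the validation screen held 17277813 to 21358926 reads, with medians of 1121 to 1395 reads per guide, and its plasmid library held 9907604. Between 2 and 15 guides had no reads in a genome-wide cell library, and between 119 and 265 in a validation cell library. Guides against olfactory and vomeronasal receptor genes served as guides without a known role in these cells. Their log2 ratios of GFP-high over GFP-low for 5xT71BS had SDs of 0.127 and 0.132 in the genome-wide pools and 0.509 in the validation library, where counting error alone gives 0.067, 0.068 and 0.073. Scores below are median log2 ratios over the guides of a gene, ± SD over 5 guides unless another number is given. A gene is called where the guide permutation test gave a Benjamini-Hochberg adjusted p under 0.05.

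In the genome-wide screen, the 5xT71BS reporter was compared between GFP-high and GFP-low cells to find genes whose loss alters its level. Guides against Trim71 itself were enriched in GFP-high cells, with a score of 1.92 ± 1.27 and 5 of 5 guides above 0. Guides against Lin28a, which encodes an RNA-binding protein that blocks maturation of let-7 microRNAs, were enriched as well, at 1.38 ± 0.70 with 4 of 5 guides above 0. Guides against Ago2, the Argonaute protein that can cut its target RNA, had the lowest score of any gene tested, -2.61 ± 0.57 with 5 of 5 guides below 0. The microRNA processing genes Xpo5, Dgcr8, Dicer1 and Drosha were also depleted from GFP-high cells, with scores of -1.85 ± 0.99, -1.67 ± 0.44 (4 guides), -1.58 ± 1.13 and -1.44 ± 0.64.

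Among the 3 genes of TRIM71 with its regulators, Trim71 and Lin28a were called higher and Lin28b, at -0.08 ± 0.07, was not called. Of the 6 microRNA biogenesis genes, 4 fell and 0 rose, while the dicer partners Tarbp2 and Prkra scored 0.14 ± 0.20 and -0.05 ± 0.09 and were not called. The miRISC core had 3 genes higher, 1 lower and 3 not called of 7. The 3 that rose were Tnrc6a, Tnrc6b and Tnrc6c, which encode the GW182 scaffold proteins that Argonautes recruit, with scores of 0.28 ± 0.75, 0.62 ± 0.21 and 0.43 ± 0.45. Ago1, Ago3 and Ago4 scored -0.01 ± 0.17, -0.06 ± 0.15 and -0.06 ± 0.05. In the 4EHP-GIGYF list, the cap-binding repressor Eif4e2 and its partners Gigyf2 and Gigyf1 rose by 0.95 ± 0.52, 0.78 ± 0.21 and 0.71 ± 0.03, and Zfp598 scored 0.06 ± 0.07. The counts of these 4 lists were the same when adjusted over the list alone. Sbno2, the actin genes Capzb, Cap1 and Actb, and the RNA-binding protein gene Ybx1 were among the 10 genes of highest score, at 2.28 ± 0.50, 2.13 ± 0.62, 2.11 ± 0.88, 1.82 ± 0.57 and 1.51 ± 0.21. Tbx3, a transcription factor of naive stem cells, and Elof1, a transcription elongation factor, followed Ago2 at the low end, at -2.21 ± 0.78 and -2.14 ± 0.50 (4 guides).

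The guide permutation test with Benjamini-Hochberg adjustment called 1027 of 17912 genes in this comparison, 435 higher and 592 lower. The smallest adjusted p of this test, 0.0004, belonged to 90 genes at the smallest p the permutations can give, 2e-06, and Trim71, Lin28a, Ago2, Xpo5, Dgcr8, Dicer1 and Drosha were among them. With the unsorted cells in place of a sorted fraction, 380 genes were called in GFP-high over unsorted cells and 434 in unsorted over GFP-low cells. Among the genes named here, the call of Tnrc6a ended without its most extreme guide and by limma (adjusted p = 0.061 and 0.21), that of Tnrc6c with the mean over guides and by limma (adjusted p = 0.089 and 0.097) and that of Dicer1 by limma (adjusted p = 0.051), each with Benjamini-Hochberg adjustment.

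The control reporter was compared in the same way, to measure effects that do not need the TRIM71 sites. Among the highest scores were those of Cap1, at 2.79 ± 1.20, the capping protein gene Capzb, at 2.68 ± 0.80, the actin turnover gene Wdr1, at 1.96 ± 0.65, and the actin gene Actb, at 1.89 ± 0.82. Guides against Xrn1, the exonuclease that degrades decapped RNA, were enriched in GFP-high cells at 1.31 ± 0.70. The lowest scores belonged to Elof1, at -1.88 ± 0.84 (4 guides), Supt5, at -1.76 ± 0.61, and Ssrp1, at -1.76 ± 0.51, followed by Arpc4 of the actin-nucleating Arp2/3 complex at -1.67 ± 0.66. Trim71 and Lin28a rose here too, by 0.39 ± 0.31 and 0.38 ± 0.22, and Ago2 scored 0.17 ± 0.22 and was not called.

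Of the microRNA biogenesis genes, Dgcr8 and Drosha rose with the control reporter, by 0.34 ± 0.31 (4 guides) and 0.31 ± 0.30, and the other 4 were not called, while 5 of the 6 rose when adjusted over the list alone. None of the 7 miRISC core genes was called, and the count adjusted over the list alone was also 0. Eif4e2 and Gigyf1 rose by 0.25 ± 0.14 and 0.32 ± 0.05, which made 2 of 4 genes of 4EHP-GIGYF repression, and 3 of 4 adjusted over the list alone. Eif4e2 was depleted in culture. When random guides were drawn separately from depleted genes, its control call ended, with an adjusted p of 0.4 in the guide permutation test, and 1 of the 4 rose. In all, 924 of 17916 genes were called by the guide permutation test with Benjamini-Hochberg adjustment, 426 higher and 498 lower, and 2429 had an unadjusted p under 0.05. With the mean over guides in place of the median, 235 genes were called, and Trim71, Lin28a, Dgcr8, Drosha, Eif4e2 and Gigyf1 were no longer called with this reporter.

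**Figure D1:**
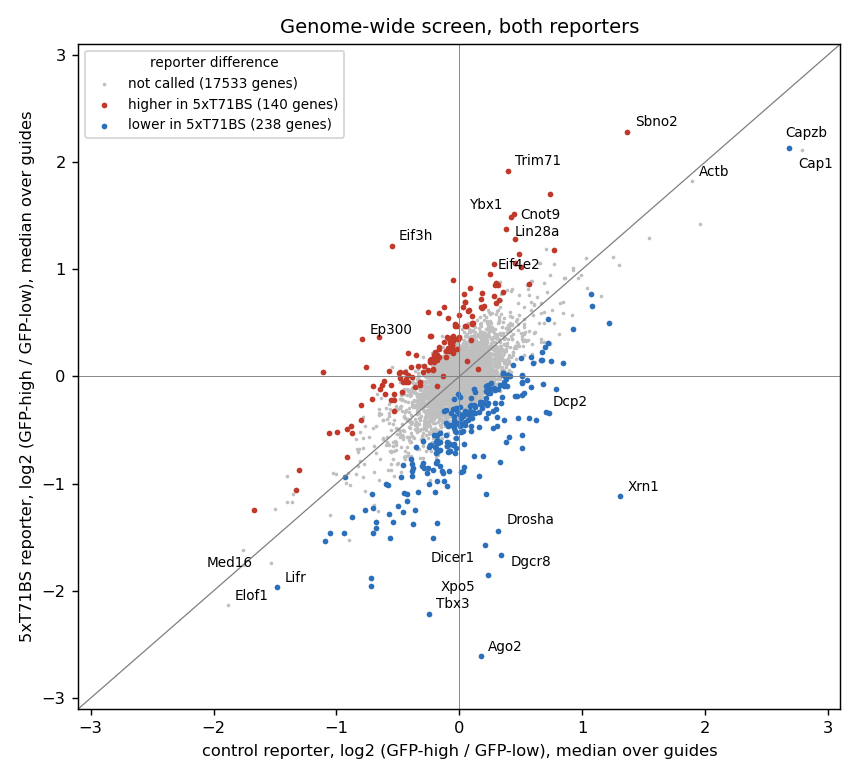
Each point is a gene of the genome-wide screen, placed by its median log2 ratio of GFP-high over GFP-low. The control reporter is horizontal and 5xT71BS vertical. Colour marks genes called in the reporter difference. The ratio was higher in 5xT71BS than in the control for 140 of them and lower for 238. Ago2, Dgcr8, Dicer1, Drosha and Xpo5 lie far below the diagonal line of equal ratios, Trim71 lies above it, and Actb, Med16 and Elof1 lie near it.

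The reporter difference, the 5xT71BS ratio minus the control ratio of the same guides, tested which effects differed between the reporters. Each reporter was carried by its own cell line, so effects of the reporter and of the line cannot be told apart. It was lowest for Ago2, at -2.86 ± 0.76, and for Xrn1, at -2.43 ± 1.02, and next lowest for Xpo5, Dgcr8, Dicer1 and Drosha at -2.08 ± 1.18, -1.98 ± 0.67 (4 guides), -1.98 ± 1.39 and -1.79 ± 0.89. It was highest for Trim71, at 1.94 ± 1.06, followed by the translation initiation factor gene Eif3h at 1.51 ± 0.24, the acetyltransferase gene Ep300 at 1.30 ± 0.21 and the mRNA export factor gene Thoc3 at 1.16 ± 0.42. Ybx1, Lin28a and Cnot9, a subunit of the CCR4-NOT deadenylase, had differences of 1.09 ± 0.25, 1.00 ± 0.51 and 0.88 ± 0.33. For Dicer1, 3 of 5 guides lay below 0, against 5 of 5 for Ago2, Xpo5 and Drosha.

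In the difference, Trim71 and Lin28a were 2 of 3 genes called in their list, and 4 of 6 microRNA biogenesis genes fell, with the same counts adjusted over the list alone. The miRISC core had Tnrc6b higher, at 0.58 ± 0.18, and Ago2 lower, and adjusted over the list alone 3 genes were higher and 1 lower. Tnrc6a and Tnrc6c, at 0.31 ± 0.55 and 0.26 ± 0.35, were not called over all genes. Eif4e2, Gigyf2 and Gigyf1 rose by 0.71 ± 0.49, 0.49 ± 0.24 and 0.41 ± 0.05, which made 3 of 4 genes of their list both over all genes and adjusted over the list alone. Gigyf2 was depleted in culture, and its adjusted p became 0.12 when random guides were drawn separately from depleted genes, while that of Eif4e2 became 0.035, both by the guide permutation test with Benjamini-Hochberg adjustment. The calls of Gigyf2 and Gigyf1 also ended with the mean over guides (adjusted p = 0.063 and 0.084), that of Gigyf2 with abundance-matched random guides (adjusted p = 0.054) and that of Eif4e2 by limma (adjusted p = 0.1), each with Benjamini-Hochberg adjustment.

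The same test called 378 of 17915 genes in the difference, 140 higher and 238 lower, and 1762 had an unadjusted p under 0.05. Of the 140, 70 were called higher with 5xT71BS, 50 were called lower with the control, 4 of them both, and 24 were called with neither. Of the 238, 166 were called lower with 5xT71BS, 67 were called higher with the control, 18 of them both, and 23 were called with neither. With the mean over guides in place of the median, 84 genes were called, 48 higher and 36 lower. Across genes, which are not independent replicates, the scores of the reporters correlated with r = 0.574. Both reporters were called higher for 200 genes and lower for 277, where independent lists of these lengths would share 10.3 and 16.4. Of these 200 and 277 genes, 29 and 54 were also called in the difference, although both reporters moved the same way. The reporters were called in opposite directions for 22 genes, all of which were also called in the difference. Caprin1, Eif3h, Ep300 and Thoc3 were the 4 higher with 5xT71BS and lower with the control, and 18 genes, with Dcp1a, Dcp2, Dgcr8, Drosha, Edc4, Med26 and Xrn1 among them, were lower with 5xT71BS and higher with the control. Caprin1 was named after its values were seen. The 5xT71BS calls of Ep300 and Thoc3 ended with the mean over guides, while their genome-wide difference calls held in all 14 alternatives. In the validation difference the reported test called neither, and each was called in 1 of 14 alternatives.

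**Figure D2:**
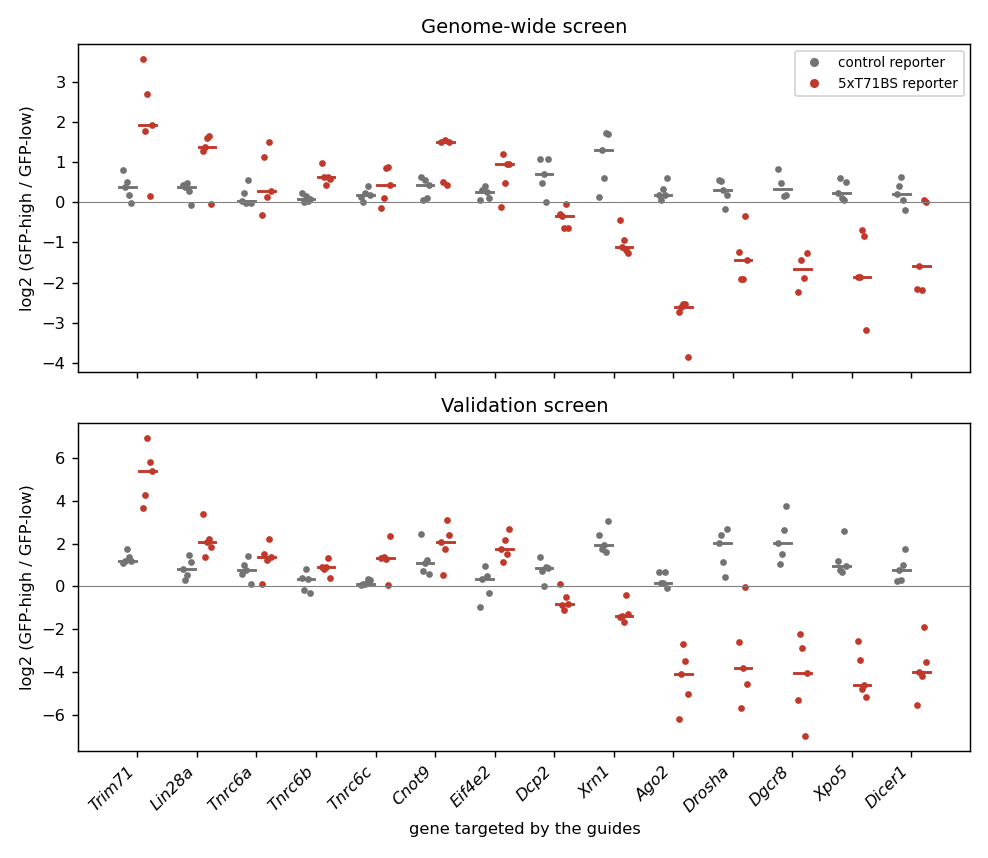
Each point is 1 guide, placed by its log2 ratio of GFP-high over GFP-low with the control reporter (grey) and with 5xT71BS (red) in the genome-wide screen (upper panel) and the validation screen (lower panel), and bars mark medians over guides. With 5xT71BS the Ago2 guides lay below 0 in both screens and the Trim71 guides above 0.

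Several genes of decapping and 5'-3' decay split between the reporters. Of 16 decapping and 5'-3' decay genes, 2 rose and 8 fell with 5xT71BS, 5 rose and 0 fell with the control, and 0 rose and 8 fell in the difference. These counts were 2 and 8, 7 and 0, and 1 and 8 when adjusted over the list alone. Xrn1 scored -1.12 ± 0.33 with 5xT71BS and was called. The decapping enzyme gene Dcp2 and its cofactor genes Edc4 and Dcp1a had 5xT71BS scores of -0.33 ± 0.26, -0.41 ± 0.10 and -0.39 ± 0.06 and control scores of 0.70 ± 0.45, 0.63 ± 0.28 and 0.48 ± 0.08, and all 3 were called with both reporters and in the difference. Their 5xT71BS calls ended with the mean over guides, and those in the genome-wide difference held in all 14 alternatives. In the validation difference the reported test called none of the 3. There Dcp2, Edc4 and Dcp1a stayed below 0 in every alternative and were called in 1, 5 and 2 of 14. Lsm1 and Lsm3, parts of the ring that binds deadenylated RNA, scored -0.88 ± 0.23 and -0.97 ± 0.62 with 5xT71BS and were not called with the control. Pan2 and Pan3, which encode a deadenylase, fell with 5xT71BS, at -0.88 ± 0.22 and -0.90 ± 0.34, and in the difference, at -0.95 ± 0.15 and -0.74 ± 0.35, and both scored -0.14 with the control, where they were not called.

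The 14 genes of the CCR4-NOT deadenylase did not move together. With 5xT71BS, 3 rose and 6 fell, and adjusted over the list alone 3 rose and 7 fell. Cnot9 rose by 1.49 ± 0.57 with 5xT71BS and by 0.42 ± 0.25 with the control, while Cnot3 scored -0.81 ± 0.33 and -0.30 ± 0.14 and Cnot1 scored -0.67 ± 0.51 and -0.83 ± 0.41. Cnot1 and Cnot3 were among genes depleted in culture, and with random guides drawn separately from such genes their 5xT71BS calls ended, at adjusted p = 0.14 and 0.054 in the guide permutation test with Benjamini-Hochberg adjustment. In the difference 1 gene rose, Cnot9, and 2 fell, and adjusted over the list alone 3 rose and 4 fell. With the random guides drawn separately, the difference of Cnot3, -0.47, was no longer called (adjusted p = 0.52 in the same test), and 1 gene fell. Of 10 nonsense-mediated decay genes, 2 rose and 2 fell with 5xT71BS, or 2 and 3 adjusted over the list alone. Smg5 and Smg6 rose by 0.48 ± 0.05 and 0.42 ± 0.12, and Upf2 scored -0.46 ± 0.21. With the control, 2 rose and 3 fell, or 4 and 3 adjusted over the list alone, with Smg5 and Smg9 among the higher and Upf1 and Upf2 among the lower. None of these 10 was called in the difference, and adjusted over the list alone 1 was higher and 2 were lower. Smg8 came closest, at -0.39 ± 0.12 with an adjusted p of 0.05 in the guide permutation test.

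Guides against pluripotency genes were mostly depleted from GFP-high cells. Of 17 genes of the pluripotency network, 1 rose and 14 fell with 5xT71BS, 2 rose and 9 fell with the control, and 2 rose and 10 fell in the difference, or 1 and 14, 2 and 10, and 3 and 12 adjusted over the list alone. The receptor genes Lifr and Il6st of the cytokine LIF, which sustains these cells in culture, scored -1.97 ± 0.91 and -1.53 ± 0.48 with 5xT71BS and -1.48 ± 0.77 and -1.09 ± 0.29 with the control. Tbx3, Tfcp2l1 and Klf5 encode transcription factors of naive stem cells, and their differences were -1.31 ± 0.65, -1.12 ± 0.17 and -0.91 ± 0.41. Sox2 and Pou5f1 fell with both reporters and were called higher in the difference, at 0.63 ± 0.59 and 0.38 ± 0.25. Both were depleted in culture, and these differences had adjusted p = 0.057 and 0.33 in the guide permutation test with Benjamini-Hochberg adjustment when random guides came separately from depleted genes.

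Mediator, which links transcription factors to RNA polymerase II, gave similar results with both reporters. Of its 32 genes, 0 rose and 22 fell with 5xT71BS, 1 rose and 20 fell with the control, and 1, Med26, fell in the difference, or 26, 28 and 2 adjusted over the list alone. Med26 was depleted in culture, and its difference had an adjusted p of 0.057 in the guide permutation test when random guides came separately from depleted genes. With those random guides, 1 other Mediator gene was called lower in the difference. Med16 scored -1.74 ± 0.85 and -1.53 ± 0.89 with 5xT71BS and control, and Med12 -1.18 ± 0.90 and -1.36 ± 1.19. Of 25 translation initiation genes, 2 rose and 12 fell with 5xT71BS and 0 rose and 10 fell with the control, and in the difference 2 rose and 5 fell. With p adjusted over the list alone, the counts were 4 and 15, 0 and 16, and 3 and 6. Of these genes 12 were depleted in culture, and with random guides drawn separately from such genes 5 fell with 5xT71BS, 3 with the control and 4 in the difference. Eif3h rose by 1.22 ± 0.31 with 5xT71BS and scored -0.55 ± 0.19 with the control, while Eif3k scored -1.21 ± 0.17 and -0.50 ± 0.10. Among 13 mRNA export genes, 5 rose and 3 fell with 5xT71BS, 1 rose and 8 fell with the control, and 3 rose and 0 fell in the difference, or 5 and 3, 2 and 10, and 8 and 0 adjusted over the list alone. With random guides drawn separately from depleted genes, these became 4 and 1, 0 and 5, and 3 and 0. Tet1, Dnmt1 and Uhrf1, of 8 DNA methylation genes, rose in the difference by 0.66 ± 0.28, 0.37 ± 0.26 and 0.46 ± 0.20, and 0 of that list were called with the control, also when adjusted over the list alone. Of 354 olfactory receptor genes, 0 were called with either reporter or in the difference.

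HUSH and SETDB1 silencing, which keeps integrated transgenes and repeats silent, had 4 of 9 genes higher and 1 lower with 5xT71BS, 5 higher and 1 lower with the control and 1 lower in the difference, or 4 and 1, 6 and 2, and 1 and 2 adjusted over the list alone. Morc2a rose by 0.74 ± 0.42 and 0.63 ± 0.36 with the reporters. Of 22 genes of the SAGA and ATAC acetyltransferases, 9 rose and 3 fell with 5xT71BS, 3 rose and 1 fell with the control, and 2 rose and 1 fell in the difference, or 9 and 6, 7 and 2, and 5 and 4 adjusted over the list alone. Of 22 genes of mTORC1 and TSC, these counts were 5 and 2, 2 and 4, and 4 and 1, or 6 and 4, 6 and 5, and 4 and 1 adjusted over the list alone. Of 15 genes of exit from pluripotency, they were 4 and 1, 2 and 5, and 3 and 0, or 7 and 2, 2 and 6, and 7 and 1 adjusted over the list alone, and Tcf7l1, a repressor of pluripotency genes, rose in the difference by 0.56 ± 0.09. Of 12 genes that write or read methylated adenosine in RNA, 0 rose and 4 fell with 5xT71BS, 1 rose and 2 fell with the control, and 1 rose and 3 fell in the difference, or 1 and 4, 2 and 2, and 2 and 4 adjusted over the list alone. Those lower in the difference included the reader gene Ythdf2 at -0.84 ± 0.40 and the writer subunit gene Rbm15 at -0.66 ± 0.22. None of 5 exon junction complex genes was called with either reporter or in the difference, and adjusted over the list alone 1 fell in the difference. Of 19 genes of p53 and growth suppression, 1 fell with 5xT71BS, and 0 were called with the control or in the difference, also when adjusted over the list alone. Of 10 genes of Polycomb repressive complex 2, 3 rose and 1 fell with 5xT71BS, 1 rose and 1 fell with the control, and 1 fell in the difference, or 4 and 3, 1 and 2, and 1 and 1 adjusted over the list alone. Of 15 RNA exosome genes, 2 fell with 5xT71BS, 1 with the control and 2 in the difference, and of 5 Pumilio and Nanos genes 2, 1 and 0 fell. With random guides drawn separately from genes depleted in culture, the call of the p53 list, Mdm2, and the call of Polycomb repressive complex 2 in the difference ended, 1 exosome gene fell with 5xT71BS and 1 in the difference, and 3 and 4 HUSH and SETDB1 genes rose with the reporters. In mTORC1 and TSC, 1 gene then fell with 5xT71BS, and 3 rose and 2 fell with the control.

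The validation screen repeated the sort after a separate transduction, with new guides for most of the library. Guides against Trim71 had a 5xT71BS score of 5.41 ± 1.29 and a difference of 4.21 ± 1.06, and a control score of 1.20 ± 0.25 that was not called. The 5xT71BS scores of Xpo5, Ago2, Dgcr8, Dicer1 and Drosha were -4.60 ± 1.09, -4.09 ± 1.36, -4.06 ± 1.91, -4.0 ± 1.32 and -3.81 ± 2.15, each with 5 of 5 guides below 0. With the control reporter, Dgcr8 and Drosha rose by 2.03 ± 1.06 and 2.03 ± 0.91, Xrn1 by 1.92 ± 0.58 and the decapping cofactor gene Edc4 by 1.52 ± 0.49. Lin28a, Cnot9 and Eif4e2 rose with 5xT71BS by 2.06 ± 0.73, 2.06 ± 0.95 and 1.74 ± 0.59 and were not called in the difference, where they scored 1.09 ± 0.75, 0.65 ± 1.06 and 1.24 ± 1.02. Tnrc6a, Tnrc6b and Tnrc6c scored 1.36 ± 0.76, 0.89 ± 0.34 and 1.32 ± 0.82 with 5xT71BS, none called over all genes, with adjusted p = 0.056, 0.16 and 0.058 by the guide permutation test.

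By list, 4 of 4 microRNA biogenesis genes in the library fell with 5xT71BS and in the difference, and 2 rose with the control, or 4 adjusted over the list alone. Of 4 miRISC core genes, Ago2 fell with 5xT71BS and in the difference and none was called with the control, where the count adjusted over the list alone was also 0. The 3 Tnrc6 genes rose with 5xT71BS when adjusted over the list alone, and 1 of them in the difference. Of 3 genes of 4EHP-GIGYF repression, 1 rose with 5xT71BS, or 3 adjusted over the list alone, and 0 in the difference, or 1 adjusted over the list alone. Both genes of TRIM71 with its regulators rose with 5xT71BS, and 1 rose in the difference, or 2 adjusted over the list alone. With the control, 0 genes of these 2 lists were called, and adjusted over the list alone 0 of 4EHP-GIGYF repression and 2 of TRIM71 with its regulators. None of 3 nonsense-mediated decay genes was called with either reporter or in the difference, also when adjusted over the list alone. The guide permutation test with Benjamini-Hochberg adjustment called 91 of 2357 genes with 5xT71BS, 67 of 2382 with the control and 12 of 2389 in the difference, and 307 genes had an unadjusted p under 0.05 in the difference.

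The 12 were Trim71, U2af1 and Tcp1, which were higher, and Ago2, Dgcr8, Dicer1, Drosha, Xpo5, Xrn1, Chordc1, Rev3l and Xab2, which were lower. Of the 9 lower genes, 6 were called lower with 5xT71BS and 5 were called higher with the control, 2 of them both. Xrn1, Rev3l and Xab2 were called higher with the control and were not called with 5xT71BS. Their entries carry the NCBI gene identifiers 636931 for Trim71, 239528 for Ago2, 94223 for Dgcr8, 192119 for Dicer1, 14000 for Drosha, 72322 for Xpo5, 24127 for Xrn1 and 66917 for Chordc1. Xrn1 had a difference of -3.57 ± 0.87 and Chordc1, a co-chaperone gene, one of -3.27 ± 2.22 with 3 of 5 guides below 0, which lost its call in 3 of 14 alternative settings. U2af1, Tcp1, Rev3l and Xab2 scored 2.41 ± 2.38 (4 guides), 2.37 ± 1.51 (4 guides), -3.61 ± 2.15 and -2.91 ± 1.17, and lost their calls in 8 of 13, 9 of 14, 3 of 13 and 3 of 14 alternative settings. The difference of Dgcr8, -7.34 ± 2.61, rested on 5 guides of which 3 had no reads in 5xT71BS GFP-high cells, and it ranged from -10.7 to -3.87 over the alternatives.

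**Figure D3:**
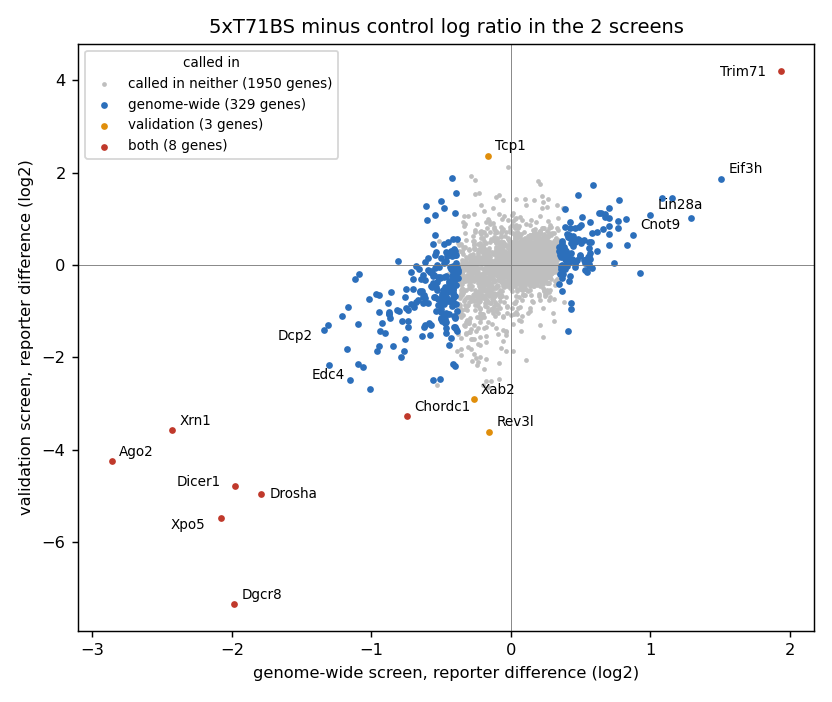
Each point is a gene tested in both screens, placed by its reporter difference, the 5xT71BS log2 ratio minus the control log2 ratio, in the genome-wide screen (horizontal) and in the validation screen (vertical), and coloured by the screen or screens in which it was called. The 8 genes called in both lie at the lower left, except Trim71 at the upper right.

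The screens shared 2265 genes tested with 5xT71BS, 2283 with the control and 2290 in the difference. Across these genes, which are not independent replicates, scores correlated with r = 0.754, 0.622 and 0.538. Of genes called in the genome-wide screen, 89.1, 83.1 and 83.4% had the same sign in the validation screen, against 60.1, 59.2 and 60.2% of genes not called there. Called the same way in both screens were 73, 52 and 8 genes, where independent lists would share 15.41, 6.78 and 0.97. Called in opposite directions were 3, 0 and 0 genes, among them Mms19, at -0.39 ± 0.34 and 2.16 ± 1.73 with 5xT71BS, which was depleted in culture. The 8 were Ago2, Chordc1, Dgcr8, Dicer1, Drosha, Trim71, Xpo5 and Xrn1, and with validation guides absent from the genome-wide libraries these 8 and Csnk1a1, a casein kinase gene, were called. The validation library held 338 of the 378 genes of the genome-wide difference, so its genes may have been chosen on that screen, and the share of its genes that were called is not a share of all genes.

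Guide abundance in unsorted cells over the plasmid library was compared on day 8 to find genes needed for growth. Guides against genes of the ribosome, the proteasome, the spliceosome and RNA polymerase II were depleted in both lines. The median scores were -3.06, -2.54, -2.10 and -2.32 in the 5xT71BS line and -2.37, -2.10, -1.55 and -2.34 in the control line. In the 5xT71BS line, 32 of 48 ribosome genes, 30 of 30 proteasome genes, 21 of 25 spliceosome genes and 10 of 10 RNA polymerase II genes fell, and in the control line 31, 29, 19 and 9. Counted with p adjusted over the list alone, 44, 30, 24 and 10 fell in the 5xT71BS line and 41, 29, 23 and 9 in the control line. Mdm2, which holds p53 in check, scored -3.11 ± 0.82 and -2.56 ± 0.62, and Trp53, the p53 gene, rose by 0.71 ± 0.34 and 0.56 ± 0.34. Dppa4 and Dppa2, genes of early embryonic chromatin, had the highest scores in the 5xT71BS line, 1.13 ± 0.21 (3 guides) and 1.08 ± 0.42 (4 guides), and differed from the control line by 0.54 ± 0.17 and 0.46 ± 0.17, both called. The scores of Ago2, Dgcr8, Dicer1, Drosha and Xpo5 in the 5xT71BS line lay between -0.67 and 0.22, and none was called.

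**Figure D4:**
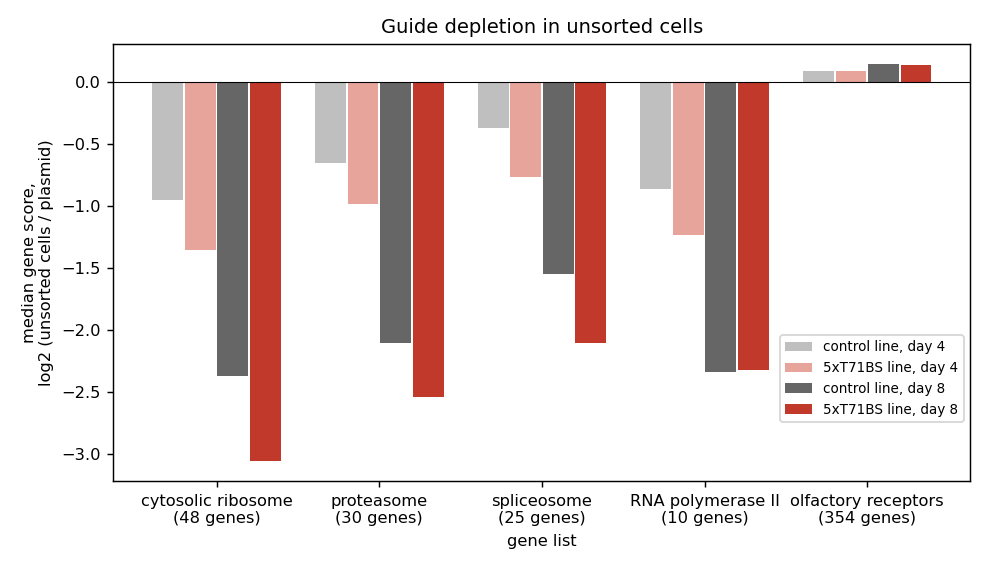
Bars show the median gene score, the log2 ratio of unsorted cells over plasmid, of 4 lists of widely needed genes and of olfactory receptor genes, for both lines on days 4 and 8. The medians of the 4 lists were lower on day 8 than on day 4 in both lines, and those of the receptor genes were above 0.

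The guide permutation test with Benjamini-Hochberg adjustment called 124 genes higher and 898 lower in the 5xT71BS line and 72 higher and 718 lower in the control line. Lower in both lines were 669 genes, where independent lists would share 36.0. Both lines were divided by the same plasmid libraries, and scores of 2 simulated unchanged lines against those plasmids had a covariance of 0.009 and a correlation of r = 0.37 across genes, which are not independent replicates, against 0.233 and r = 0.933 observed. The simulated lines had 0 calls each, so they give no value for the overlap. Day 8 over day 4, where the lines share no library, gave 736 genes lower in both, where independent lists would share 43.3. Its covariance was 0.121 and its correlation r = 0.886 across genes. That ratio spans fewer days of culture, so its lower covariance does not measure the part of the plasmid libraries. Part of the day 8 excess may come from the shared plasmid libraries.

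Depleted genes entered the sort comparisons more often. Of 947 genes called lower on day 8 in either line, 944 were tested in the 5xT71BS sort, where 32.4% were called, against 4.25% of other genes, and 946 in the reporter difference, where 11.5% were called, against 1.59%. The median SD over guides was 0.262 for depleted genes and 0.119 for others with 5xT71BS. With random guides drawn separately from depleted genes, 4.03% of depleted genes were called with 5xT71BS and 0.95% in the difference, so many sort calls of depleted genes rest on the choice of random guides. The 5xT71BS calls of Cnot1, Sox2 and Pou5f1 ended (adjusted p = 0.14, 0.38 and 0.45), and their control calls held (adjusted p = 0.0029, 0.00095 and 0.012), by the guide permutation test with Benjamini-Hochberg adjustment. By list, the genes lower with 5xT71BS and with the control became 2 and 1 of 14 in CCR4-NOT, 17 and 16 of 32 in Mediator and 12 and 9 of 17 in the pluripotency network. Of the ribosome, proteasome, spliceosome and RNA polymerase II genes, 9, 5, 2 and 4 were lower with 5xT71BS by the reported test, and 1, 0, 0 and 0 with those random guides. Trim71, Lin28a, Ago2, Dgcr8, Dicer1, Drosha, Xpo5 and Xrn1 were not among the depleted genes.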

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

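The tests in this part of read depth, guide scatter, random guide sets, exchanged labels, other guides, culture loss and EGFP matches were chosen only after the results were seen, as was the comparison of the unsorted lines, and the reporter differences were planned. The ratio of GFP-high over GFP-low differed between the reporters for 378 genes in the genome-wide screen and for 12 genes in the validation screen. Guide abundance in unsorted cells of day 8 differed between the 2 lines for 573 genes, of which 527 were lower in the 5xT71BS line. Outside the named guides, 3 validation guides without a gene symbol were depleted from GFP-high cells of both reporters. Guide 2 had log2 ratios of -7.41 with 5xT71BS and -8.36 with the control, guide 3 of -6.81 and -8.13, and guide 4 of -8.53 and -6.83, while guide 1 of the same label had -0.31 and -0.12.

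The 3 depleted guides without a symbol may target the reporter itself. Of the 4 guides of that label, 3 matched an EGFP coding sequence over 20 bases beside the motif that Cas9 needs, these 3 were the depleted ones, and no other guide in any library matched. Their share of reads in GFP-low cells exceeded the plasmid share by log2 values of at least 2.05, the highest being 2.68. Sorting alone would raise that share for guides that lower GFP. The validation screen had no unsorted library, so partial loss of these guides from the culture could not be assessed. The EGFP sequence was written from general knowledge, so the reporter sequence used in these cells stays unchecked.

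Fewer genes were called in the reporter difference of the validation screen, 12 of 2389 (0.5%), than of the genome-wide screen, 378 of 17915 (2.11%). Fewer reads per guide were argued against, since counting error accounts for an SD of 0.103 of receptor guides where 0.7 was measured. Median reads per guide were also not lower, at 1121 to 1395 in validation cell libraries and 644 to 1274 in genome-wide ones. Scatter of unaffected guides was 3.93 and 4.12 times that of the genome-wide pools, which is consistent with a noisier sort or fewer cells per guide. The labels give a coverage of 500 per guide at transduction in the validation screen and 700 in the genome-wide screen, and do not give the number of sorted cells. A library rich in responding genes could also widen the random guide sets, since 244 genes were called with random sets from receptor guides alone, against 12. Those receptor sets keep the scatter of receptor guides and still gave 244 calls. Guides of depleted genes may scatter more than receptor guides. In the genome-wide difference, the median SD over guides was 0.301 for depleted genes and 0.158 for others. Random guides matched on abundance gave 56 calls in the validation difference. The 244 calls therefore need not be responding genes, and they do not exclude scatter. How much each contributed stays open, and no biological explanation was tested.

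Guides against Ago2, Dgcr8, Dicer1, Drosha and Xpo5 were depleted from GFP-high cells of the 5xT71BS reporter. Exchanged fraction labels in 1 line were argued against by a positive correlation between the reporters across other genes, r = 0.479 and 0.589 in the 2 screens, where genes are not independent replicates. Off-target cutting by the genome-wide guides was argued against by calls of 5 of 5 genes on guides absent from those libraries. For loss of cells in culture, other genes in the same range of day 8 depletion, -0.67 to 0.22, were counted. Of these, 8 of 13407 (0.06%) had a sort score as low. This range holds mostly genes that were not depleted, so a low share was nearly assured and does not decide the question. The 5 genes themselves were not called depleted in either line. As a hypothesis, loss of microRNAs may raise TRIM71, whose transcript is a target of let-7, and so lower the reporter. TRIM71 levels were not analysed here, so this stays untested.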

How the results depend on the processing

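The settings with genes depleted by day 8 left out, with random guides drawn within depleted and other genes, with random guides from receptor genes and with only new validation guides were chosen after seeing the data, and all other settings were planned. Of 120 counts of calls under alternatives, 89 stayed within 1.5 times the reported count and 31 did not. Of 2647 values of named genes, 2413 kept their direction and their side of the threshold, 113 lost a call, 94 gained one and 27 reversed, none of which was called before or after. In the genome-wide screen, Rev3l went from -0.05 to 0.02 with 5xT71BS and from 0.15 to -0.04 with the control, and Xpo5 and Tnrc6a from 0.23 to -0.07 and from 0.04 to -0.12 with the control, for GFP-high against unsorted cells. With unsorted against GFP-low cells, the control scores of Tnrc6b, Pan2, Pan3, G3bp1, Xab2 and Tcp1 became -0.06, 0.07, 0.03, 0.01, -0.26 and -0.04, and without the most extreme guide that of Pan2 became 0.01. With the mean of guides and with limma alike, Tcp1 became 0.3 with 5xT71BS, -0.06 with the control and 0.36 in the difference. In the validation screen, both gave control scores of -0.03 for Gigyf2, 0.18 for G3bp1 and -0.14 for Ybx1, leaving out the most extreme guide gave -0.17 for Ep300 with 5xT71BS and 0.29 for Tcp1 with the control, and new guides alone gave G3bp1 0.9 with the control and -0.38 in the difference. Of 697 list medians, 688 moved by less than the SD over the members of the list and 9 moved further. That SD is a wide band for lists of mixed direction. The reporter differences of Trim71, Ago2, Dicer1 and Xpo5 were called under all 14 alternatives in both screens, while those of Dgcr8 and Drosha in the validation screen were called under 13 of 14, with adjusted p of up to 0.052 and 0.12 in the guide permutation test or limma with Benjamini-Hochberg adjustment. Those of Gigyf2, Gigyf1 and Eif4e2 in the genome-wide screen were called under 10 of 13, 13 of 14 and 12 of 13, with adjusted p of up to 0.12, 0.084 and 0.1, and that of Chordc1 in the validation screen under 11 of 14, with adjusted p of up to 0.4. With the mean of guides, 279 genes were called in the genome-wide 5xT71BS comparison, 235 with the control and 84 in the difference, where 57.1% were higher, against 37.0% with the median. With GFP-high against unsorted cells, 380 and 218 genes were called for 5xT71BS and control, and with unsorted against GFP-low cells 434 and 328. Without genes depleted by day 8, 667, 592 and 235 genes were called for 5xT71BS, control and difference, where the same genes held 721, 650 and 269 calls in the reported test. In the validation screen, limma called 200 genes with 5xT71BS and 122 with the control, abundance-matched random guides gave 192, 167 and 56 for 5xT71BS, control and difference, leaving out the most extreme guide of each gene gave 157, 128 and 34, and random guides from receptor genes gave 621, 496 and 244. A pseudocount of 50 gave 105 with the control and 20 in the difference, and a mean count of at least 100 gave 109 with the control. Other scalings and the centring on olfactory receptor guides called 10 genes in the validation difference, 10% higher, against 12 genes and 25%. Such settings move scores and random guide sets together, so this change reflects almost only the random draws. Genes called in both screens numbered 42 with abundance-matched random guides, 16 with a pseudocount of 50, 83 with random guides from receptor genes and 19 without the most extreme guide, against 8. For depletion in culture, limma called 1561 genes in the 5xT71BS line, and day 4 against plasmid called 295 there and 145 in the control line. Beyond the scalings and centring, the causes of these shifts were not tested. No paired analysis was possible within a screen, because the labels carry no replicate numbers and each group held 1 library. Pairs across screens or pools exist and were not tested gene by gene. Depth limits little here, since counting error of receptor guides was 0.067 in the first genome-wide pool and 0.073 in the validation library for 5xT71BS, against measured SDs of 0.127 and 0.509, while guides without reads in a sorted fraction, as for Dgcr8 in the validation screen, leave the size of a ratio to the pseudocount.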

Other observations

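The 8 gene lists and the genes named in this part, and all tests on them, were chosen only after the results were seen, and the tests were those of the report. Elongator, which modifies tRNA wobble bases, had 6 of 6 genes lower with 5xT71BS in the genome-wide screen, 5 lower with the control and 5 lower in the difference, with Elp3 at -1.36 ± 0.42, -0.54 ± 0.17 and -0.74 ± 0.26. In the validation screen none of the 6 was called, with medians of -1.36 and -0.41 for the reporters and -1.08 for the difference, while 6, 2 and 3 had an unadjusted p under 0.05. The G3BP stress granule proteins differed between the reporters, with 5 of 12 genes higher and 1 lower in the difference. G3bp1 and G3bp2 rose there by 0.78 ± 0.34 and 0.77 ± 0.13, and their partner Ubap2l fell, at -0.68 ± 0.21. In the validation screen none of 9 of these genes was called in the difference, where G3bp1, G3bp2 and Ubap2l scored 1.41 ± 1.52, 0.95 ± 0.51 and -0.03 ± 0.53 and 4 had an unadjusted p under 0.05. With 5xT71BS, G3bp2 and Ybx1 rose there by 1.74 ± 0.43 and 1.73 ± 0.91. On new guides alone, the difference of G3bp1 was -0.38. The ER membrane protein complex had 5 of 10 genes lower with 5xT71BS and 6 lower with the control, and 4 rose in the difference, Emc4 by 0.41 ± 0.11 and Emc7 by 0.36 ± 0.17. Validation gave calls for none of 2, with medians of -0.96 and -0.65 for the reporters and -0.14 for the difference.

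Of 22 ESCRT genes, which act in membrane scission and sorting, 13 rose with 5xT71BS and 8 with the control, and 3 rose in the difference. Vps28 scored 0.92 ± 0.34 and 0.96 ± 0.51 with the reporters. None of 9 ESCRT genes was called in the validation screen with either reporter or in the difference, and 5, 3 and 0 had an unadjusted p under 0.05. Of 22 Fanconi anaemia genes, which repair DNA crosslinks, 10 rose with 5xT71BS, 11 rose and 1 fell with the control, and 1 fell in the difference, with Fancl at 0.62 ± 0.11 and 0.59 ± 0.07. In the validation screen 4 of 8 Fanconi anaemia genes rose with 5xT71BS and 1 with the control. With random guides drawn separately from genes depleted in culture, 7 rose with 5xT71BS, 9 rose and 1 fell with the control, and 0 were called in the difference in the genome-wide screen. Of 18 genes of the Arp2/3 and WAVE complexes, 9 fell with 5xT71BS and 12 with the control, and 2 rose and 1 fell in the difference, with Actr2 at -1.06 ± 0.26 and -1.33 ± 0.32. Of 4 such genes in the validation screen, 0 fell with 5xT71BS, where 3 had an unadjusted p under 0.05, and 3 fell with the control. With random guides drawn separately from genes depleted in culture, 2 Arp2/3 and WAVE genes rose and 0 fell in the genome-wide difference. Of 12 genes of actin capping and turnover, 5 rose with 5xT71BS, 6 rose and 1 fell with the control, and 1 fell in the difference. With random guides drawn separately, 6 rose and 0 fell with the control. In the validation screen 4 of 6 actin genes rose with each reporter. Of 7 genes of LIF receptor signalling, 4 fell with 5xT71BS and 5 with the control, and in the difference 1 rose and 4 fell, among them Jak1 at -0.78 ± 0.28. With random guides drawn separately from genes depleted in culture, 0 rose and 2 fell in the difference, and Lifr and Stat3 had adjusted p = 0.31 and 0.44 in the guide permutation test with Benjamini-Hochberg adjustment. Of 5 LIF receptor genes in the validation screen, 4 fell with 5xT71BS and 3 with the control, and none was called in the difference, where 2 had an unadjusted p under 0.05, with Jak1 at -1.99 ± 0.96 and Lifr at -0.14 ± 1.07.

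Among 243 guides present in both genome-wide pools, guide ratios correlated between the pools with r = 0.597 for 5xT71BS, 0.452 for the control and 0.414 for the difference, across guides that are not independent replicates. Without guides beyond 0.5 in size, r was 0.186, 0.373 and 0.083.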
